A study of Candida albicans with 6 samples.

How the data were processed

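Poly(A) RNA of the yeast Candida albicans was sequenced as paired-end reads on an Illumina instrument, per the labels' protocols, in 6 libraries: 3 from cultures treated with the agent labelled FIP and 3 from untreated cultures, called blank here. The series' title speaks of polycatechol-based iron predators, polymers that carry the iron-binding catechol group. Logarithmic-phase cells grown in SD medium at 30 °C received 16 µg/mL of FIP for 3 h. The labels' treatment protocol gives 37 °C for this step and the series' design text gives 30 °C, so the temperature of the treatment is not settled. The design text names strain ATCC 10231 for all samples, whereas the strain labels count up from 10231 in blank replicate 1 to 10236 in FIP replicate 3. The samples are treated here as 1 strain. The design text calls the 3 samples of each group biological replicates.

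The authors deposited a table of whole-number read counts per gene for the 6 libraries, with TPM and FPKM beside them, per the file headers. HISAT2 is named in the submitters' processing notes, with no version. The counting tool, its strand setting, the annotation release and the genome build are not given in the sources used here. The TPM values were deposited by the authors, per the file headers, and served here only to describe levels. FPKM was not used. All 6030 gene names and coordinates in the table are identical to those of a RefSeq gene table of assembly ASM18296v3, made from strain SC5314, so coordinates are given on that assembly, 1-based. It is a reference from another strain. Each row is a protein-coding gene. A pair of names that a spreadsheet had turned into dates was restored from the locus tags. Because the strand setting is unknown, reads of overlapping genes cannot be told apart, and near-identical paralogs could have exchanged reads.

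A second deposited table holds the authors' own comparison of the groups as log2 fold changes with p-values and adjusted p-values, per the file headers, for 811 genes. The tool behind it is not given in the sources used here. The smallest absolute log2 fold change in it is 0.50 and the largest p-value 0.0492.

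Depth ran from 27775485 to 32973633 counts per library. The common biological coefficient of variation was 0.0681. With 3 samples against 3, an exact permutation test of a single value cannot give a two-sided p below 0.1, so genes were tested with a model that shares information on the spread across genes. Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM scaling, the filterByExpr filter on group, a robust quasi-likelihood fit with group as the only term, and a two-sided quasi-likelihood F test with Benjamini-Hochberg adjustment over the 5911 genes that passed the filter. A gene was called at an adjusted p under 0.05. Of the 119 genes left out, 23 had no count in any library. The standard error (SE) of a log2 fold change was taken as its absolute value divided by the square root of F. On counts simulated for FIP against blank over the same 5911 genes, with 50 genes changed at each fold size, the procedure recovered 58% of 1.25-fold changes, 94% of 1.5-fold, 98% of 2-fold and 100% of 4-fold changes, with 9 false calls. With no change simulated it called 1 gene and 0 lists. Genes were simulated independently of each other and without a deviating library, whereas estimated correlations within the real lists reached 0.487. The 0 lists therefore do not show how often correlated lists pass by error. Far more genes were called in the data than were changed in the simulation. The recovered shares and false calls therefore need not carry over to the data.

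A set of 23 gene lists was fixed from general knowledge before the data were examined, and so were the tests, the alternatives and the rule for naming genes. Lists were tested with camera (limma 3.58.1) on the signed square root of F, with a preset inter-gene correlation of 0.01 and adjustment over the 23 lists. Camera with a correlation estimated per list and the rotation test fry were run beside it. The camera run with estimated correlations worked from the counts and not from F. Values given "with an estimated correlation" therefore differ from the main test in more than the correlation. The pair of iron uptake lists was also tested together, as a single test with no adjustment. Counts of called members are over all genes tested, and a count "adjusted over the list alone" uses only the p-values of that list. The naming rule took the 6 largest rises and 6 largest falls among called genes with a mean count of at least 50 and no overlap between groups, 14 iron genes whatever their result, and up to 3 called members per list with the largest change and a mean count of at least 50. CSA2, a haem-uptake gene of the fixed set, had 2, 2 and 0 counts in the blank libraries and 0 in the FIP libraries and was not tested. NAG4, of the drug efflux list, had 0 to 4 counts per library and was not tested either. Other fixed symbols had no row of that name in the deposited table, where many rows carry only a locus tag, and were not tested: 10 of 24 symbols were tested for iron-sulphur cluster assembly, 15 of 20 for copper, zinc and manganese, 16 of 20 for heat shock, 26 of 29 for the respiratory chain, 12 of 14 for ATP synthase and 8 of 10 for haem synthesis. The regulator, gluconeogenesis, oxidative stress, hypha and replication lists each lacked 1 symbol. Some results are not reported here. Genes outside this rule are said to have been chosen after their values were seen.

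Alternatives were RLE, upper-quartile and library-total scaling, no filter, a mean count of at least 10, DESeq2 1.42.0, limma voom, a replicate block, an adjusted p under 0.01, and leaving out each library in turn. A test of annotation terms had been planned and was not run, because the tables used here carry no term column. Alternatives planned for normalized units did not apply to counts. Figures were drawn with matplotlib 3.10.9.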

Results

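The transcriptome of Candida albicans, a yeast pathogen of humans, was measured after 3 h with 16 µg/mL of FIP and in untreated cells. The series' design text names iron sequestration by FIP as the mechanism to be investigated. Each group held 3 biological replicates. Total counts were 31593965, 27775485 and 30435399 in blank replicates 1 to 3 and 31457547, 32973633 and 32343503 in FIP replicates 1 to 3. Between 5980 and 5994 genes had at least 1 count in a library. Replicates of a group differed by more than sampling noise, with chi-square per degree of freedom from 5.40 to 55.1, so each library was counted on its own. The first principal component held 77.4% of the variance and separated the groups. Blank replicate 1 stood apart from the other blanks on the second component, which held 10.1%, and its chi-square per degree of freedom was 41.6 against blank 2 and 55.1 against blank 3, compared with 10.3 between blanks 2 and 3.

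**Figure D1:**
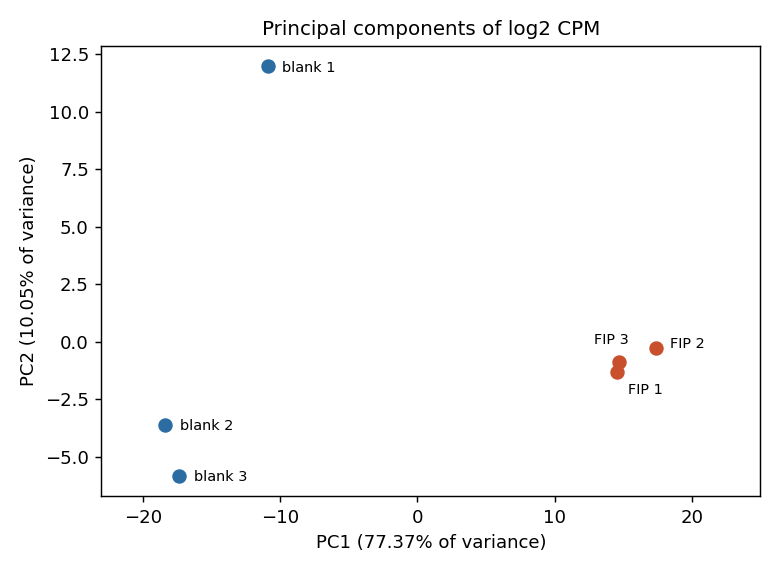
Principal components of log2 CPM (counts scaled by library size) over the tested genes, 1 point per library, with blank libraries in blue and FIP libraries in red. The groups part along PC1 (77.4% of variance), and blank 1 lies at 11.96 on PC2 while blank 2 lies at -3.62 and blank 3 at -5.84.

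FIP changed the level of 2814 of 5911 tested genes (47.6%), mostly by small amounts. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1365 genes were higher and 1449 lower with FIP, and the median absolute log2 fold change of called genes was 0.35. A change of at least 2-fold was called in 174 genes, 96 higher and 78 lower. The 3 FIP libraries did not overlap the 3 blank libraries in 3388 genes (57.3%), where chance gives 10%. Leaving out FIP replicate 2 gave 907 higher genes, and 802 were higher at an adjusted p under 0.01.

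The 6 largest rises included an adjacent pair on chromosome 1 and PGA37, a gene for a putative GPI-anchored surface protein. The open reading frame CAALFM_C111260CA (chromosome 1, 2473804 to 2473941) rose from 1.70 ± 0.441 to 27.3 ± 1.58 TPM (SD, n = 3), a log2 fold change of 3.89 ± 0.22 (SE). CAALFM_C111270WA, at 2475446 to 2476084 on the same chromosome, rose by 2.65 ± 0.10. CAALFM_CR06550CA (chromosome R, 1396675 to 1397004) rose by 3.61 ± 0.19, CAALFM_C202910WA by 2.86 ± 0.13 and CAALFM_C200750WA by 2.23 ± 0.10. PGA37 (chromosome 5, 965156 to 965782) rose by 2.35 ± 0.38, with 638 counts in blank replicate 1 against 202 and 258 in the other blanks. The largest fall was that of CAALFM_C504940WA (chromosome 5, 1078889 to 1080637), from 392 ± 57.0 to 41.2 ± 4.96 TPM (SD, n = 3), with a log2 fold change of -3.24 ± 0.12. PHO84, a high-affinity phosphate transporter (chromosome 1, 2522233 to 2523870), was 5.97-fold lower and CFL11, of the ferric reductase-like family (chromosome R, 1433878 to 1436097), 5.68-fold lower. MCD1, a cohesin subunit, had a log2 fold change of -2.07 ± 0.10, CAALFM_C202220CA of -2.05 ± 0.18 and ARO10, an aromatic decarboxylase, of -1.96 ± 0.13. Adjusted p-values of these 12 genes lay between 2.59e-08 and 0.00438.

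Genes of high-affinity iron uptake rose in part. FTR1, an iron permease (chromosome 1, 3113601 to 3114746), rose from 245 ± 20.9 to 488 ± 32.1 TPM (SD, n = 3), with a log2 fold change of 1.00 ± 0.07 and an adjusted p of 2.48e-06. The ferric reductase gene FRE10 (chromosome 4, 923039 to 925159) was 2.14-fold higher. CFL4, a reductase-like gene, was 2.53-fold higher at a low level of 1.62 ± 0.0974 TPM with FIP. The multicopper oxidase gene FET34 was 1.46-fold higher and the siderophore transporter gene SIT1 1.33-fold. Of 18 genes on the reductive and siderophore uptake list, 9 were higher and 3 lower, and the counts adjusted over the list alone were also 9 and 3. The 3 lower genes were FTR2, a paralog of FTR1, at -0.71, FRE7 at -0.83 and FRE30 at -0.86; they were named because they are few, after their values were seen. The list passed the camera test (median log2 fold change 0.27, adjusted p = 0.0143), with adjusted p = 0.485 with an estimated correlation. Without blank replicate 1, the library that stood apart, its median was 0.15 and its adjusted p 0.0708, and without FIP replicate 1 the adjusted p was 0.0608.

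Of 7 tested haem-uptake genes, 2 were higher and 1 lower (median 0.15, mean -0.06, camera adjusted p = 0.649), with the same counts when adjusted over the list alone. The median was 0.10 with no low-count filter, 0.09 without blank replicate 1 and 0.08 without FIP replicate 1, where 1 member was higher. HMX1, the haem oxygenase, was 1.49-fold higher and FRP2, a reductase-like gene, 1.22-fold higher. FRP2 was not called without FIP replicate 1. PGA10, a haem-binding surface protein gene, was 3.18-fold lower. RBT5, the gene of another haem receptor, had a log2 fold change of 0.15 ± 0.11 with an adjusted p of 0.291. Taking both uptake lists as 25 genes, 11 were higher and 4 lower, with a median of 0.18 (camera p = 0.0104, and p = 0.21 with an estimated correlation). Without blank replicate 1 that median was 0.11.

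Regulators of iron homeostasis moved in opposite directions. SEF1, an activator of iron uptake genes (chromosome R, 479677 to 482430), was 1.74-fold higher, from 6.99 ± 1.02 to 12.1 ± 1.27 TPM (SD, n = 3). HAP43, a CCAAT-binding factor subunit that represses iron-using genes when iron is scarce (chromosome 1, 2464977 to 2466881), was 1.72-fold higher, from 9.68 ± 0.276 to 16.6 ± 0.505 TPM. SFU1, a GATA-type repressor of uptake genes (chromosome 1, 2195272 to 2196825), was 1.66-fold lower, from 5.11 ± 0.71 to 3.07 ± 0.253 TPM. CCC1, which carries iron into the vacuole, was 1.81-fold lower, and FTH1, the gene of a vacuolar iron exporter in yeasts, 1.94-fold higher. Adjusted p-values of these 5 genes lay between 3.14e-06 and 0.0015. Of 13 genes on the regulator and storage list, 5 were higher and 2 lower, also when adjusted over the list alone (median 0.08, camera adjusted p = 0.178). That median was 0.05 without FIP replicate 1, 0.12 without FIP replicate 3 and 0.04 under upper-quartile scaling. The list holds activators beside a repressor, and a vacuolar importer beside an exporter. Its median and camera test look for a common direction, so they could not show opposite moves of such genes.

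**Figure D2:**
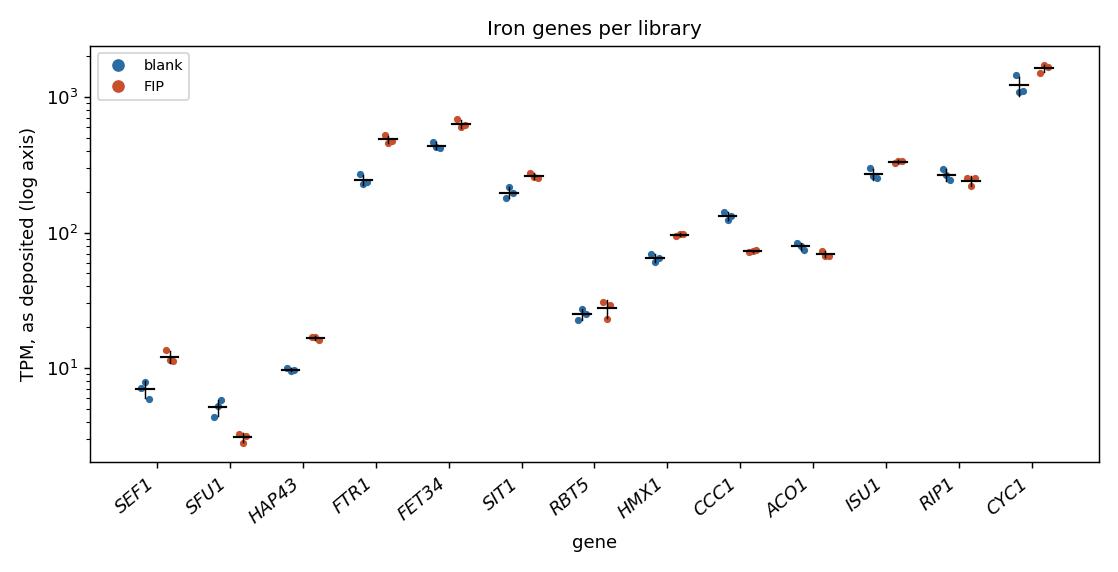
Deposited TPM of 13 iron genes on a log axis, with 1 point per library, blank in blue and FIP in red, and black bars for the mean ± SD of 3 libraries. SEF1, HAP43, FTR1, FET34, SIT1 and HMX1 lie higher in every FIP library than in every blank library, SFU1 and CCC1 lie lower, and RBT5 and RIP1 overlap.

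Iron-using enzymes showed no common direction. Of 21 genes for iron-sulphur or haem enzymes, 6 were higher and 6 lower, with equal counts adjusted over the list alone (median -0.05, camera adjusted p = 0.489). BIO2, biotin synthase, was 2.46-fold lower and CCP1, cytochrome c peroxidase, 2.08-fold lower, while LEU1 of leucine synthesis was 1.73-fold higher. ACO1, aconitase, had a log2 fold change of -0.19 ± 0.05 that was not called without FIP replicate 2 or FIP replicate 3. CYC1, cytochrome c, had 0.43 ± 0.10, and RIP1, the Rieske protein, -0.14 ± 0.07 with an adjusted p of 0.146. Leaving out FIP replicate 3 gave 3 lower members, and the median was -0.09 without blank replicate 1 or under upper-quartile scaling, -0.10 without blank replicate 3 and -0.08 without FIP replicate 1. Of 24 symbols fixed for iron-sulphur cluster assembly, only 10 had a row of that name in the table; of these 10, 6 were higher and 0 lower, also over the list alone (median 0.16, adjusted p = 0.127), among them ISA2 at 0.34, ERV1 at 0.32 and the scaffold gene ISU1 at 0.32. The count of higher members was 3 without blank replicate 2, FIP replicate 2 or FIP replicate 3, and 3 under upper-quartile scaling. Of 8 genes of haem synthesis, 0 were higher and 3 lower, also over the list alone (median -0.13, adjusted p = 0.127): HEM13 was 1.74-fold lower, COX15 1.21-fold and HEM14 1.15-fold. HEM14 was not called without blank replicate 3, FIP replicate 1 or FIP replicate 2.

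Genes of DNA replication and the cell cycle showed the largest shift of any fixed list. Of 36 tested members, 25 were lower and 7 higher, and 26 and 7 when adjusted over the list alone. The list's median log2 fold change was -0.58 (camera adjusted p = 4.06e-20, and adjusted p = 0.0148 with an estimated correlation). It was the only list past the threshold in both camera runs. Its estimated correlation, 0.00465, was below the preset 0.01, so the correlation does not account for the higher p. RNR1, the large subunit of ribonucleotide reductase (chromosome 2, 639344 to 641908), fell from 147 ± 9.95 to 56.5 ± 6.38 TPM (SD, n = 3), with a log2 fold change of -1.37 ± 0.08. POL1, a DNA polymerase, was 2.51-fold lower and SMC3, a cohesin subunit, 2.50-fold lower. The 7 higher members were RNR3 and 6 histone genes, HHT2, HHT21, HTA1, HTB1, HTA2 and HHF1, with log2 fold changes of 0.30 to 0.51; they were named after their values were seen.

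**Figure D3:**
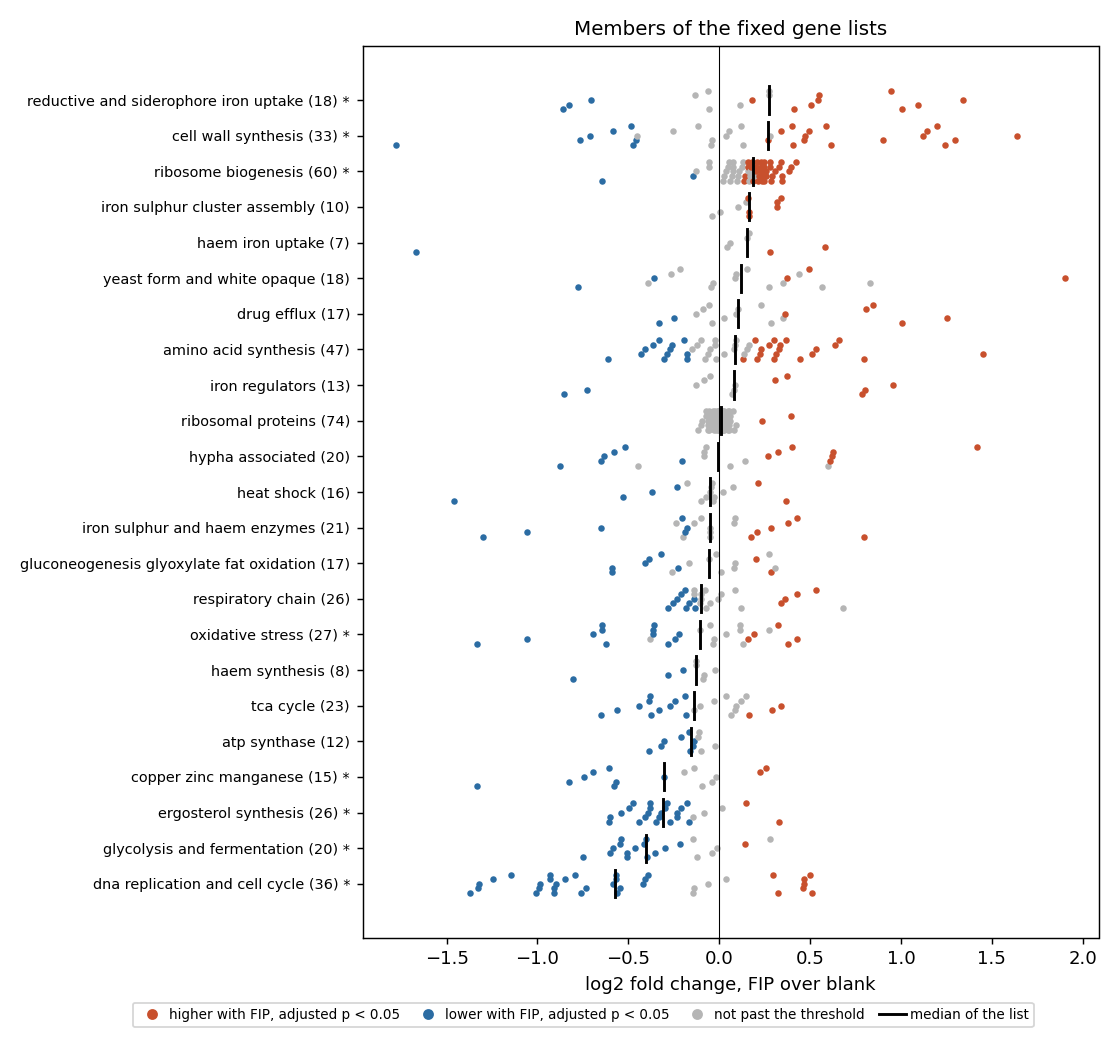
Log2 fold change (FIP over blank) of every tested member of the 23 fixed lists, with the number tested in parentheses, called genes in red (higher) or blue (lower), others in grey, and a black bar at each list's median. An asterisk marks the 8 lists past the camera threshold with the preset correlation; the replication and cell cycle list has the lowest median, -0.58.

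Glycolysis and sterol synthesis genes fell by modest amounts. Of 20 glycolytic and fermentative genes, 14 were lower and 1 higher, also over the list alone (median -0.40, camera adjusted p = 4.96e-06, and adjusted p = 0.405 with an estimated correlation). The hexokinase gene HXK2 (chromosome R, 995376 to 996830) fell from 4369 ± 67.2 to 2580 ± 160.0 TPM (SD, n = 3), PGI1 was 1.52-fold lower and the pyruvate kinase gene CDC19 had a log2 fold change of -0.58. The higher gene was TYE7, a transcription factor, at 0.14, named after its value was seen. No member was higher without blank replicate 2, FIP replicate 2 or FIP replicate 3, and 2 were without blank replicate 1. Of 26 ergosterol genes, 21 were lower and 2 higher, and 22 and 2 over the list alone (median -0.31, camera adjusted p = 0.000285, and adjusted p = 0.503 with an estimated correlation). ERG28 and ERG10 were each 1.52-fold lower and ERG24 1.45-fold lower. The 2 higher members, UPC2 and ERG25, were named after their values were seen; 0 or 1 member was higher when any library was left out.

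Mitochondrial lists did not pass the list test. Of 12 ATP synthase genes, 8 were lower and 0 higher, also over the list alone (median -0.15, adjusted p = 0.0733), with ATP2 at -0.38, ATP1 at -0.32 and ATP3 at -0.30. The lower count was 5 without FIP replicate 1 or 3 and 4 without FIP replicate 2, and the adjusted p was 0.0485 under upper-quartile scaling. Of 23 genes around the citrate cycle, 3 were higher and 11 lower, also over the list alone (adjusted p = 0.16), with FUM11 at -0.56 and LAT1 at -0.44. FUM11 overlaps RPR2, and LAT1 was not called without blank replicate 2 or 3 or FIP replicate 2 or 3. The higher count was 6 without blank replicate 1 and 1 without FIP replicate 3, and the lower count 7 without FIP replicate 2. Of 26 respiratory chain genes, 4 were higher and 9 lower, also over the list alone (adjusted p = 0.634), with YMX6, an alternative NADH dehydrogenase, at 0.53, CYC1 at 0.43 and COX17 at 0.36. Those counts were 7 higher without blank replicate 1 and 5 lower without FIP replicate 1. Of 17 genes for gluconeogenesis, the glyoxylate cycle and fat oxidation, 2 were higher and 6 lower, also over the list alone (adjusted p = 0.428), with FAA2-1 at -0.59, ACS1 at -0.59 and FAA2-3 at -0.41. FAA2-3 was not called without blank replicate 2, FIP replicate 2 or FIP replicate 3, and the higher count was 4 without blank replicate 1 and 1 without blank replicate 2 or FIP replicate 2.

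Cell wall genes rose more often than they fell. Of 33 members, 16 were higher and 7 lower, and 16 and 8 over the list alone (median 0.27, camera adjusted p = 0.000876, and adjusted p = 0.485 with an estimated correlation). CHS2, a chitin synthase (chromosome R, 1926708 to 1929737), was 3.11-fold higher and PHR2, a glucan-modifying enzyme, 2.45-fold higher. The chitinase gene CHT2 (chromosome 5, 919760 to 921511) was 3.43-fold lower. Of 15 tested genes of copper, zinc and manganese handling, from 20 fixed symbols, 8 were lower and 2 higher, also over the list alone (median -0.30, camera adjusted p = 0.00465, and adjusted p = 0.485 with an estimated correlation). SOD1, the copper-zinc superoxide dismutase (chromosome 4, 460935 to 461644), fell from 283 ± 9.23 to 111 ± 4.08 TPM (SD, n = 3), FRE7 was 1.77-fold lower and the zinc transporter gene ZRT1 1.68-fold lower. The higher pair was CUP2 and SMF12, named after their values were seen, and only 1 was higher without any single library other than blank replicate 1. Of 27 oxidative stress genes, 12 were lower and 5 higher, also over the list alone (median -0.10, camera adjusted p = 0.0143, and adjusted p = 0.485 with an estimated correlation). SOD1 was 2.52-fold lower, CCP1 2.08-fold and SOD3, a manganese superoxide dismutase, 1.62-fold. The higher count was 3 without blank replicate 2 and 2 without any single FIP library. The list's median was -0.23 without blank replicate 1 and -0.025 without blank replicate 3. As fixed, the oxidative stress list shares SOD1 and SOD3 with the copper, zinc and manganese list and CAT1 and CCP1 with the enzyme list. It shares SOD5 with the hypha list and EBP1 with the yeast-form list. FRE7 is on both the reductive iron uptake list and the copper, zinc and manganese list. Other lists share members too.

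Ribosome biogenesis genes rose slightly, and ribosomal protein genes were mostly not called. Of 60 biogenesis genes taken by their symbols, 35 were higher and 2 lower, and 37 and 2 over the list alone (median 0.19, camera adjusted p = 0.000332, and adjusted p = 0.597 with an estimated correlation). UTP8 was 1.31-fold higher and NSA2, which overlaps CAALFM_C306390WA, 1.34-fold higher, while MAK32 was 1.56-fold lower. Symbols alone decided membership, so MAK32 need not act in ribosome biogenesis. Without FIP replicate 1 the higher count was 23, and the lower count was 4 without blank replicate 1 and 1 without any other single library. Of 74 ribosomal protein genes, 2 were higher and 0 lower, also over the list alone (median 0.01, adjusted p = 0.649): RPS27A at 0.39 and RPL7 at 0.24. Without blank replicate 1, 5 were lower, and without FIP replicate 1, 1 was; the median lay between -0.04 and 0.03 in all settings run. Of 47 amino acid synthesis genes, 19 were higher and 12 lower, also over the list alone (median 0.09, or 0.05 without blank replicate 2 or under upper-quartile scaling, adjusted p = 0.16), with GDH3, an NADP-linked glutamate dehydrogenase, at 1.45, LEU1 at 0.79 and HIS3 at 0.66.

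Among drug efflux genes, 5 of 17 were higher and 2 lower, also over the list alone (median 0.10, adjusted p = 0.132), with the transporter genes QDR3 at 1.26 and QDR2 at 1.01 and the lipid-translocating exporter family gene RTA3 at 0.85. Without blank replicate 1, 10 were higher, the median was 0.24 and the list passed (adjusted p = 0.00116). Without any other single library, 0 or 1 was lower, and the median was 0.06 under upper-quartile scaling and 0.16 with no low-count filter. Of 20 hypha-associated genes, 7 were higher and 6 lower, and 8 and 6 over the list alone, with a median of -0.01, a mean of 0.05 and a camera adjusted p of 0.649. The median lay between -0.05 and 0.03 in all settings run. SAP5, a secreted protease gene with close paralogs that could share its reads, was 2.68-fold higher, KIP4 1.83-fold lower and HYR1 1.57-fold lower. HYR1 was not called without blank replicate 1. Of 18 yeast-form and white-opaque genes, 3 were higher and 2 lower, also over the list alone (adjusted p = 0.166). RHD1 was 3.74-fold higher, YWP1, a yeast-form wall protein gene, 1.71-fold lower and WH11 1.41-fold higher, a call that WH11 lost without blank replicate 1 or FIP replicate 3. Of 16 heat shock genes, 2 were higher and 4 lower, also over the list alone (adjusted p = 0.16), with HSP31 at -1.46, HSP70 at -0.53 and HSP104 at -0.37.

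List tests with the preset correlation gave 8 of 23 lists past the threshold, and 1 with an estimated correlation. Regrouping the 6 libraries into other sets of 3 and 3 gave up to 10 lists past the preset-correlation test and 0 called genes. Each of those sets mixes blank and FIP libraries. Part of the FIP effect therefore stays in the contrast and the rest widens the spread, so these counts do not show what libraries without an effect would give.

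The authors' deposited table of the same comparison lists 811 genes, 357 up and 454 down. Of the 809 that were tested here, all 809 had the same sign and 794 were called in the same direction. In the authors' deposited table, 16 listed genes have an adjusted p of 0.05 or more. Of 795 genes called here with an absolute log2 fold change of at least 0.5, that table lists 792.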

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

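Across 84 named genes and 14 alternatives, 1158 of 1176 fold changes kept their direction and side of the threshold, 18 lost the call and 0 reversed. Most of these genes were named because they were called with large changes, which favours their stability. Over all genes, leaving out a library other than blank replicate 1 lost 452 to 804 of the 2814 calls. The counts of higher and lower genes were within 1.5 times of 1365 and 1449 under every change of scaling, filter and tool; 802 genes were higher at an adjusted p under 0.01, because the threshold is stricter. Leaving out 1 library gave 907 to 1630 higher genes, 1111 to 1756 lower genes and 159 to 223 changed at least 2-fold; the lowest came without FIP replicate 2, or blank replicate 2 for 2-fold changes, and the highest without blank replicate 1, where 2728 of the 2814 calls were kept among 3386. The lists past the threshold numbered 7 or 8 when a library was left out, 1 with an estimated correlation and 18 by fry, which does not compare a list with other genes. The median of the iron uptake lists ran from 0.11 to 0.27 with a library left out (p = 0.00581 to 0.0474) and stayed at 0.18 with an estimated correlation (p = 0.21). That of iron-using enzymes ran from -0.10 to -0.05, and fry gave an adjusted p of 0.034 for the same median, -0.049. Among the 23 lists, the direction reversed in 3 of 368 values, none of them past the threshold in either setting: respiratory chain without blank replicate 1 (adjusted p = 0.83), hypha-associated genes without FIP replicate 1 (0.789) and ribosomal proteins without blank replicate 1 (0.735). With a library left out, these adjusted p-values ran from 0.534 to 0.83, from 0.28 to 0.796 and from 0.262 to 0.789. The cause was not tested. With the replicate block, 1201 genes were higher and 1314 lower, and 8 lists passed; of the named genes, LAT1 and FAA2-3 had adjusted p-values of 0.0634 and 0.0583. Same-numbered samples did not deviate together (correlations -0.09, -0.15 and 0.00052), and no blank library correlated best with its own number. The smallest simulated changes were recovered in 58% of cases. That simulation changed 50 genes at each fold size, against 2814 genes called in the data, so the share need not carry over. The term test was not run, for want of terms.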

Other observations

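The gene groups in the first 2 paragraphs, and the tests of mixed RNA, of library scaling, of S phase, of zinc or copper shortage and of iron shortage, were chosen after the values were seen. Some genes taken here as calcium-related stood among the larger rises. CRZ1, RTA2 and PLC2 had been seen as large rises before the group was made. CRZ1, the calcineurin-dependent transcription factor, rose 4.35-fold, from 7.20 ± 1.48 to 31.1 ± 0.937 TPM (SD, n = 3), RTA2 4.65-fold and PLC2 4.41-fold. Of 8 further genes of calcium transport and signalling, 4 were higher and 1 lower: the channel genes CCH1 (2.67-fold) and MID1 (1.39-fold), CRZ2 (2.67-fold) and the vacuolar calcium pump gene PMC1 (2.76-fold) rose, and the vacuolar exchanger gene VCX1 fell 1.34-fold. CNB1 at -0.06, RCN1 at 0.03 and PMR1 at -0.14 on the log2 scale were not called. PMC1 had 16100 counts in blank replicate 1 against 8003 and 7916 in the other blanks. By camera these 8 genes had an adjusted p of 0.0269 over 13 such groups, and an adjusted p of 0.14 with an estimated correlation. The 13 groups include some picked for their large changes, which lowers the adjusted p of the others.

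Beside PHO84, the phosphate transporter gene PHO89 had a log2 fold change of -1.08 ± 0.30, the transcription factor gene PHO4 -0.54 ± 0.10 and PHO113 -0.67 ± 0.12. GIT1, a glycerophosphodiester transporter gene, had 0.46 ± 0.08. Of 11 such genes, with PHO84 included, 5 were lower and 2 higher (camera adjusted p = 0.0406 over 13 groups, and adjusted p = 0.236 with an estimated correlation). PHO84 had been seen as a large fall before the group was made, so these p-values are not an independent test. The maltose genes MAL2 and MAL31 were 3.65-fold and 3.74-fold lower; MAL31 lies near CAALFM_C504940WA on chromosome 5, the gene with the largest fall, and MAL2 on chromosome R. Outside the replication list, the mismatch repair genes MSH6 and PMS1 were 3.12-fold and 2.43-fold lower, and MSH3 had a log2 fold change of 0.04 with an adjusted p of 0.608. Of 11 leucine and valine synthesis genes, 8 were higher and 0 lower (camera adjusted p = 0.00269, and adjusted p = 0.305 with an estimated correlation). LEU1, already seen to be higher, is among them, so this is not an independent test either. Of 9 lysine genes, 5 were lower and 2 higher (camera adjusted p = 0.241, and adjusted p = 0.567 with an estimated correlation).

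The 6 libraries form 10 splits into 3 and 3, too few for a share under 0.05. Every split but the real one mixes blank and FIP libraries in each set. Few called genes in those splits are thus built in, and their lists still carry part of the FIP effect, so they decide nothing here. The real split called 2814 genes and 174 at least 2-fold, and 1 split, the real one, gave as many; the highest of the others was 0 for both. For the fixed lists the real split gave 8 past the threshold, 6 splits gave as many, and the highest other gave 10.

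Blank replicate 1 lay toward the FIP libraries. Its distance to the FIP mean was 0.857 of that of the other blanks, and 0.858 after all libraries were thinned to the same total, which argues against depth. Across genes, which are not independent replicates, its difference from blank 2 correlated with the FIP effect measured against blank 3 (r = 0.43), and its difference from blank 3 with the effect against blank 2 (r = 0.34). Mixed-in FIP RNA would move strongly falling genes toward FIP; 24% of 25 such genes moved away, short of the 25% set as the bound, and the implied share had a median of 13.9% for falls and 9.58% for 40 rises with a wide spread, so a mixture may still be part of it and cannot be told apart from a culture that differed. No biological explanation was tested: every sample carries a strain label of its own, against the 1 strain of the design text, so a strain difference stays open and untested.

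The DNA replication list fell, and matching on mean count and gene length did not give the fall, since the lowest median of 10000 random lists was -0.17. Fewer cells in S phase would lower histone genes too, and these had a median of 0.46, with 7 of 9 higher and 0 lower. The group had a camera adjusted p of 0.0269 over the added groups, and an adjusted p of 0.434 with an estimated correlation. This argues against fewer S-phase cells as the whole cause, although most of these genes had been seen higher before the test was chosen. Other shifts of cells over the cell cycle were not tested. The list's own median was -0.58 at its highest over 4 scalings, with a jackknife SE of 0.046 over left-out libraries. Less the median of all genes it was -0.58 under each, so the list fell relative to other genes. The median of all genes moved only from -0.034 to 0.00855 over these scalings. They could not have brought the list to 0, so they do not decide whether scaling has a part. A hypothesis that stays open is that FIP lowers the replication genes through their shared regulation apart from histones, which may be followed up with cell cycle measurements. The strain labels differ between replicates of the same group as well as between groups, and a strain effect on this list was not tested.

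Iron uptake genes were higher only in part: of 25 genes, 11 were higher, 4 lower and 10 not called (median 0.18, camera p = 0.0104, and p = 0.21 with an estimated correlation), with a median of 0.11 without blank replicate 1. Their own median was 0.14 at its lowest over 4 scalings, with a jackknife SE of 0.085 over left-out libraries. Less the median of all genes it was 0.17 under each. The median of all genes moved only from -0.034 to 0.00855, so these scalings could not have brought the lists to 0 and do not decide whether scaling has a part. Shortage of zinc or copper would raise the zinc and copper uptake genes of the fixed list; ZRT1, PRA1 and CTR1 were lower, ZRT2 had -0.10 (adjusted p = 0.199) and CTR2 -0.02 (adjusted p = 0.824), a median of -0.58, which argues against it, although the lower ones were noticed before the test was chosen. Iron shortage may lower iron-using enzymes as a class, but the fixed list went both ways (median -0.05, camera adjusted p = 0.489), which decides nothing. Iron shortage from FIP is a candidate explanation for SEF1, HAP43, SFU1 and FTR1 that these data cannot separate from other effects of the polymer. No iron-supplemented or chelator control was analysed here. Of 15 ferric reductase-like genes, grouped after their values were seen, 5 were higher and 4 lower (camera adjusted p = 0.394 over 13 groups). CFL11 was among the lower. Strain labels differ within groups too, yet libraries correlated at 0.994 to 0.997 in log2 CPM within groups and at 0.977 to 0.986 between them. This argues against the labelled strains as the source of the group difference, which was not tested otherwise.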
